A study of Gallus gallus with 50 samples.

How the data were processed

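RNA was measured in mucosal scrapings of the jejunum and the ileum, 2 segments of the small intestine, of male broiler chickens on day 10. The samples were hybridised to the Affymetrix chicken genome array, which reads each transcript with probe sets of short probes placed near its 3' end. There were 50 arrays from 25 birds, 5 birds on each of 5 diets, and each bird gave 1 jejunum array and 1 ileum array. The labels place the birds in 3 batches, and every batch held 1 or 2 birds of every diet. Only RNA above a set integrity score was hybridised, and part of the tissues were extracted again to reach it, according to the labels.

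The deposited values are log2 signals per probe set that the authors made with RMA (robust multi-array average, which corrects background, equalises the distributions of the arrays and summarises the probes). The labels also name limma, and no version of either tool is given in the sources used here. The values ran from 1.84 to 13.99, were written with 2 decimals, and had nearly equal quartiles on every array, so they were used as given with no further normalisation. No correction for batch is stated. Equalised distributions hide any change shared by most transcripts, so every difference below is relative to the bulk of the array. Raw scans were not used here. The number of birds per group limits the precision of every value.

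Of 38535 probe sets in the table, 153 control and reporter probe sets were left out and 38382 were tested, with no filter on dim signals. The platform annotation gave exactly 1 gene symbol to 27168 of them, which stand for 13009 genes. It gave several symbols to 177 probe sets and none to 11037. Gene IDs of 26853 probe sets matched a current chicken gene table (assembly GRCg7b), used for names only. No genome build is given for the array values, so no coordinates are stated.

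Groups were compared with limma 3.58.1 in R 4.3.3. For each segment, its 25 arrays were fitted together with diet and batch as terms, and the moderated statistics were adjusted over all probe sets by the Benjamini-Hochberg method with a threshold of 0.05. Each of the 4 supplemented diets was set against the control. Lysolecithin was set against purified LPC at the matched level, and the high level was set against the low level over both products. A moderated F-test asked whether any diet had an effect. The segments were compared with the bird as a block, since both arrays of a pair came from the same bird, and the F-test was repeated on each bird's jejunum minus ileum difference to ask whether diet effects differed between segments. All 4 comparisons with the control share the same 5 control birds, so they are not independent of one another.

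Gene groups were tested with 35 lists of genes for the pathways, cell types and contaminating tissues of a gut scraping, each gene by the probe set with the highest mean. The test was limma's camera with a preset correlation between genes of 0.01, which compares a list with the rest of the genes, adjusted over lists and the 4 diets within a segment. The list of collagens reflects the title of the study, so its direction is not independent evidence. Because a preset correlation understates the dependence of genes measured in the same birds, camera was repeated with a correlation estimated for each list, and fry tested whether a list's genes moved, on balance, one way. A list's members were also averaged per bird and compared by an exact two-sided permutation test of 5 against 5 birds, whose smallest possible p is 0.0079.

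These tests, the lists, the alternatives below and the rule for naming genes were fixed before the data were examined. By that rule the text draws on the 10 largest increases and the 10 largest decreases past the threshold per diet, the 3 highest and 3 lowest by moderated statistic where fewer than 10 passed, the 15 largest differences each way between segments, the 4 leading members of each list past its test, and a fixed set of intestinal genes. Outside the lists a gene is named by its probe set with the lowest p, which favours large values: counted after the data were seen, 102 genes were taken for calls against control over all comparisons, 80 of them had other probe sets, and in 62 of these no other one passed. Of the 224 other probe sets 28 passed and 190 had the same sign. Alternatives were no batch term, batch as a random block, brighter probe sets only, a trend and robust prior, array weights, centring on the median, both segments in 1 fit with the bird as a random block, only the 2 groups compared, and leaving out each bird in turn.

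Checks added after the data were seen were a score of segment marker genes per array, a match of each bird's 2 arrays, and an index of RNA integrity or labelling, the mean 5' minus 3' signal of 3 control transcripts. Fits without the arrays these checks put in doubt, fits with the index as a covariate, and the permutation test of list averages were added at the same time, and leaving out each bird was later extended to every list and the segments were compared within each diet. The fit was tested on simulated data that kept the spread of each probe set. Probe sets were drawn independently, so their correlation and any array out of place were not simulated. For LPC high against control in the ileum, it recovered 46 of 50 probe sets shifted by 1 on the log2 scale and 11 of 50 shifted by 0.5, among 38382 tested. At a shift of 1 the comparisons with control ranged from 38 (ileum lysolecithin low) to 47 (ileum lysolecithin high) of 50. Each simulated comparison held 50 changed probe sets at each of 0.5, 1, 2 and 4, which makes the adjusted threshold easier to pass. Recovery can therefore be lower in real comparisons with few calls, such as ileum LPC high with 0.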

Results

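Chickens received 1 of 5 feeds, and expression in the mucosa of the jejunum and the ileum was measured on day 10. The control feed had no supplement. Purified lysophosphatidylcholine (LPC), a phospholipid that has lost a fatty acid chain and acts as an emulsifier, was fed on a carrier at 9.5 g/T (LPC low) or 19 g/T (LPC high). Lysolecithin, the phospholipid mixture from which that LPC was purified, was fed at 250 g/T (lysolecithin low) or 500 g/T (lysolecithin high), which supplied the same 9.5 and 19 g/T of LPC. Each feed had 5 birds and each bird gave both segments, so there were 5 arrays per feed and segment and 50 in all. The chicks were kept in adjoining floor pens, and the labels do not say whether a feed was given in more than 1 pen, so pen and feed are not separated here.

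Most arrays carried the markers of their labelled segment. A score was formed as the mean of the 15 genes most biased to the jejunum minus that of the 15 most biased to the ileum, chosen on the other birds. Its median was 1.82 in jejunum arrays and -5.42 in ileum arrays. On the wrong side of the halfway value of -1.80 were 4 arrays: the array labelled jejunum control replicate 2 scored -5.05, jejunum LPC low replicate 4 scored -5.99, ileum LPC low replicate 1 scored 3.51 and ileum lysolecithin high replicate 4 scored 3.35. The paired arrays of 24 of the 25 birds matched their own bird best over 100 probe sets, and those of LPC low replicate 4 did not. These 5 arrays from 4 birds are called the arrays in doubt, and the counts below are also given without them. Of the arrays on their own side, the jejunum scored -1.40 to 5.41 and the ileum -6.33 to -4.56. By diet these jejunum scores were -1.27 to 5.01 in control, -1.40 to 1.57 in LPC low and 1.12 to 4.80 in LPC high birds. They were 0.75 to 4.73 with lysolecithin low and 1.82 to 5.41 with lysolecithin high. The score was not a term in any fit, so it is not separated from diet, with or without the arrays in doubt.

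**Figure D1:**
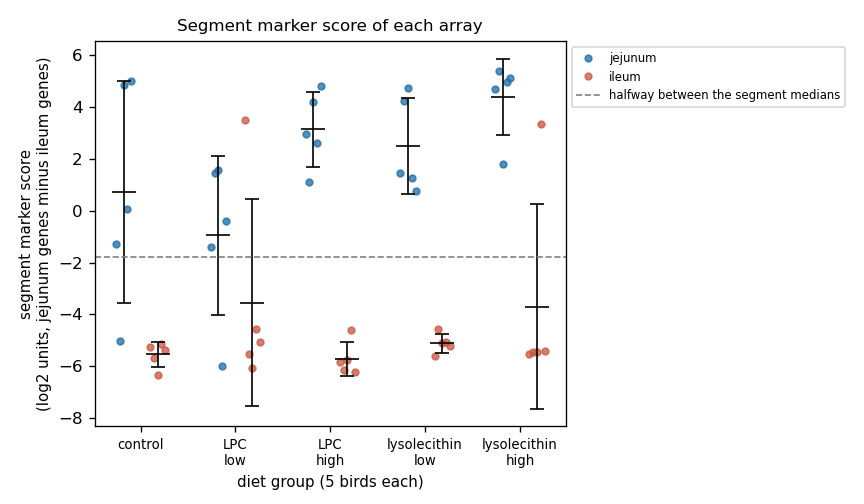
Segment marker score (log2, vertical axis) of every array by diet (horizontal axis), jejunum in blue and ileum in red, with 1 point per array, bars for the mean and SD of 5 birds and the dashed line at the halfway value of -1.80. Of the 50 arrays, 4 lie on the side of the other segment.

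Signal at the 5' end of 3 control transcripts (actin, GAPDH and EF1A) was lower than at the 3' end on average in every group, and lowest in the control birds. In the jejunum the 5' minus 3' index was -0.97 ± 0.14 (SD, n = 5) in control birds and -0.46 ± 0.10 (SD, n = 5) in LPC high birds. All 5 LPC high birds lay above all controls (exact permutation p = 0.0079, the smallest it can give; adjusted p = 0.0317 over 8 comparisons). Lysolecithin low gave -0.66 ± 0.16 (exact p = 0.0159), LPC low -0.72 ± 0.27 (exact p = 0.103) and lysolecithin high -0.64 ± 0.29 (exact p = 0.0635). In the ileum the index was -0.80 ± 0.14 in control birds, -0.56 ± 0.08 in LPC high birds (exact p = 0.0079) and -0.55 ± 0.19 in lysolecithin high birds (exact p = 0.0159). Both low diets gave -0.70 in the ileum. Counts within a segment are therefore also given with this index as a covariate.

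**Figure D2:**
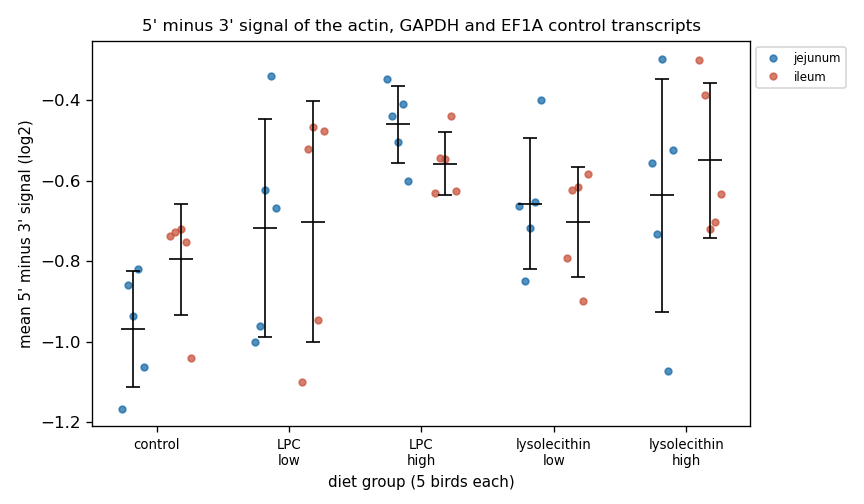
The 5' minus 3' index of 3 control transcripts (log2, vertical axis) by diet (horizontal axis), jejunum in blue and ileum in red, with 1 point per array and bars for the mean and SD of 5 birds. In the jejunum the control mean is -0.97 and the LPC high mean is -0.46.

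The comparison of jejunum with ileum asks how the segments of the same birds differ. SCARB1, a lipoprotein and lipid receptor, was among the genes most biased to the jejunum. It was higher by 3.58 ± 0.37 (log2, SE) than in the ileum, at 10.01 ± 1.39 against 6.43 ± 1.84 (SD, n = 25), and in 23 of 25 birds. CD36, a fatty acid receptor, was higher by 3.34 ± 0.31 in 24 birds, GIP, a gut hormone released on feeding, by 3.56 ± 0.45 in 22 birds, and SLC26A9, an anion transporter, by 4.56 ± 0.44 in 22 birds. Among the genes most biased to the ileum were SLC10A2, the ileal bile acid transporter, at -4.58 ± 0.69 and FABP6, the ileal bile acid binding protein, at -3.63 ± 0.60. AVD (avidin) at -4.61 ± 0.48, SLC26A3, a chloride exchanger, at -4.02 ± 0.42 and CA4, a carbonic anhydrase, at -3.94 ± 0.74 were also higher in the ileum. Past the threshold were 7567 of 38382 probe sets (limma with the bird as a block), 3807 higher in the jejunum and 3760 higher in the ileum.

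Of the 35 lists, 9 passed camera between the segments. None kept its call with an estimated correlation (adjusted p = 0.342 for lipid absorption and for bile acid handling, 0.398 to 0.849 for the other 7). Fry, which does not compare a list with the rest of the genes, passed 11 of the 35, with 8 of these 9 among them and cholesterol biosynthesis not (adjusted p = 0.0694). Dietary lipid absorption was higher in the jejunum by a mean of 0.59, with 15 of 22 members higher, among them APOA4 (1.62 ± 0.16) and APOA5 (1.98 ± 0.25), and FABP6 lower. Adjusted over the list alone, 17 were higher and 2 lower. Fatty acid oxidation was higher by 0.32 (14 of 19 members; ACADS 0.41 ± 0.05), oxidative phosphorylation by 0.24 (23 of 33) and mineral transport by 0.55 (8 of 14; SLC34A2, a phosphate transporter, 1.28 ± 0.19). Bile acid handling had a mean of -0.89, with 6 of 10 members lower in the jejunum, among them NR1H4, the bile acid receptor, at -1.05 ± 0.12, and 2 higher. Cholesterol biosynthesis (-0.24), inflammatory cytokines (-0.31; IL8L2 -2.22 ± 0.37) and ER stress (-0.20; XBP1 -0.36 ± 0.06) were lower. Brush-border enzymes and transporters had a mean of -0.01 and a median of -0.12, with 12 of 25 members lower, such as ANPEP (-0.34 ± 0.05), and 4 higher, such as SLC2A2 (2.00 ± 0.29). Without the 4 birds in doubt the differences were larger, with SLC26A9 at 5.51 ± 0.13, SCARB1 at 4.23 ± 0.27 and SLC10A2 at -5.63 ± 0.53. In that fit 9065 probe sets passed and lipid absorption passed with an estimated correlation (adjusted p = 0.0354). The 4 birds were left out for an array on the wrong side of a score of the genes most biased between the segments. The larger differences and the list call follow in part from that choice and are not added evidence.

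LPC low against control in the jejunum asks for the effect of purified LPC at the lower level. TLR3, a receptor for double-stranded RNA, rose by 1.66 ± 0.23 (log2, SE; adjusted p = 0.0211), from 7.14 ± 0.14 to 8.90 ± 0.62 (SD, n = 5), and was above all control birds in all 5. It was the only one of 38382 probe sets past the threshold (limma; 3284 at an unadjusted p under 0.05), and the other 2 TLR3 probe sets had 0.36 and 0.50 (adjusted p = 0.755 and 0.337). ZC3HAV1, an antiviral zinc finger protein, had a value of 1.47 ± 0.25 (adjusted p = 0.0826), PRDX6, an antioxidant enzyme, 1.35 ± 0.23, TSHZ2, a transcription factor, -1.04 ± 0.18 and BCL6, a transcriptional repressor, -0.94 ± 0.18 (adjusted p = 0.18), all short of it. The interferon response list was higher by a mean of 0.92 over 23 genes, 21 of them positive, with OASL at 1.70 ± 0.39 and EIF2AK2 at 1.25 ± 0.32. No member passed over all probe sets and 15 did when adjusted over the list alone. Camera gave an adjusted p of 9.88e-16, which was lost with an estimated correlation (adjusted p = 0.717). Brush-border genes were higher by 0.24 (adjusted p = 0.717 with an estimated correlation; SLC2A5, a fructose transporter, 1.42 ± 0.39), and cell cycle genes had a mean of -0.32 (0.85 likewise as an adjusted p), a call that ended without control replicate 2 (-0.15, adjusted p = 0.207). The interferon shift was 0.31, 1.23 and 1.16 in the 3 batches and 0.73 without the arrays in doubt. Without those arrays, or with the index as a covariate, 0 probe sets passed, and TLR3 had an adjusted p of 0.0857 and 0.0882. Leaving out control replicate 1, 3, 4 or 5 or LPC low replicate 2 or 4 gave 0, and leaving out LPC low replicate 5 gave 7. Array weights gave 26.

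LPC high against control in the jejunum asks for the effect of purified LPC at the higher level. CYP4V2, a fatty acid hydroxylase, rose by 1.81 ± 0.35 (log2, SE; adjusted p = 0.0452), from 9.15 ± 1.04 to 10.95 ± 0.43 (SD, n = 5). SLC25A22, a mitochondrial glutamate carrier, rose by 1.62 ± 0.28, PLA2G12B, a secreted phospholipase-like protein, by 1.36 ± 0.23, PSAP, the precursor of lysosomal lipid-degrading activators, by 1.28 ± 0.21, and MOGAT2, which builds triglyceride from absorbed fat, by 1.23 ± 0.24. The other 3 MOGAT2 probe sets had -0.20 to 0.66 and did not pass (smallest adjusted p = 0.0606). TLR3 rose by 1.41 ± 0.23 and ZC3HAV1 by 1.44 ± 0.25. Lower were RALGAPA2 (-1.13 ± 0.17; adjusted p = 0.0289; 0.12 in its other probe set, adjusted p = 0.779), a regulator of small GTPases, BCL6 (-0.97 ± 0.18), ZNF236 (-0.95 ± 0.16) and MAGI1 (-0.76 ± 0.12), a junction scaffold. In each of these 11 genes all 5 birds lay beyond all controls. In all 43 probe sets passed, 19 higher and 24 lower. The count was 2 with batch as a random block, 443 with only the 2 groups compared and 908 with array weights.

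At this level the lists past camera held lipid handling, interferon and connective tissue genes. Each call named in this paragraph was lost with an estimated correlation (adjusted p = 0.85 for each). Lipid absorption was higher by 0.49 over 22 genes (20 positive; MTTP, which assembles lipoproteins, 0.76 ± 0.17; 5 members adjusted over the list alone), and interferon response by 0.76 (19 of 23 positive; IFIT5 1.88 ± 0.51; 14 members adjusted over the list alone). No member of either list passed over all probe sets by the probe set used. The collagen list was higher by 0.44 (camera adjusted p = 0.0113; 15 of 22 positive), with COL3A1 at 1.45 ± 0.74 and COL1A1 at 1.00 ± 0.71, no member past the threshold over all probe sets or adjusted over the list alone, and 4 of 5 birds above all controls (exact p = 0.0635). The study's title names collagen, so this list is not independent evidence. Smooth muscle markers, from the muscle layer beneath the mucosa, were higher by 0.51 (MYH11 1.94 ± 0.84), basement membrane genes by 0.47 and macrophage markers by 0.39, while inflammatory cytokines had a mean of -0.30. The collagen shift was 0.09, 0.75 and 0.75 in the 3 batches, the lipid shift 0.76, 0.10 and 0.48, and the interferon shift 0.44, 1.22 and 0.97.

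Only 8 probe sets passed without the arrays in doubt, 6 of them among the 43, and 0 passed with the index as a covariate. Of the 11 genes named above, TLR3, RALGAPA2 and MAGI1 (adjusted p = 0.026 for each) were still past the threshold without those arrays by the same probe set. CYP4V2, SLC25A22, PLA2G12B and ZNF236 (0.0618 for each as an adjusted p), MOGAT2 and PSAP (0.06), ZC3HAV1 (0.0557) and BCL6 (0.0651) were not. The lipid shift was 0.30 without the arrays in doubt (adjusted p = 0.00142) and 0.32 without control replicate 2, an array in doubt. The smooth muscle call ended without control replicate 3 or 5 or LPC high replicate 3 (adjusted p = 0.0791 to 0.28), the macrophage call without LPC high replicate 3 (0.0597), and the inflammatory call without control replicate 1 or 4 or LPC high replicate 4 (0.0559 to 0.252). The basement membrane call ended without control replicate 2, 3 or 5 or LPC high replicate 2, 3 or 5 (0.0617 to 0.173). Leaving out any 1 of the 10 birds moved the count, to between 0 (without control replicate 1, for example) and 28 (without LPC high replicate 5), and the collagen call ended without control replicate 5 (adjusted p = 0.0662) or LPC high replicate 3 (adjusted p = 0.0545).

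Lysolecithin low against control in the jejunum asks for the effect of the mixture at the lower level. TLR3 rose by 1.54 ± 0.23 (log2, SE; adjusted p = 0.00998), from 7.14 ± 0.14 to 8.68 ± 0.40 (SD, n = 5), and ZC3HAV1 by 1.51 ± 0.25 (adjusted p = 0.0179), each above all controls in all 5 birds. PIK3CB, a phosphoinositide kinase subunit, fell by 1.22 ± 0.18, SPTBN5, a spectrin of the membrane skeleton, fell by 1.18 ± 0.17, and ARFGEF1, an activator of vesicle-forming GTPases, fell by 1.13 ± 0.16. Also lower were RALGAPA2 (-1.06 ± 0.16), ZNF236 (-1.04 ± 0.16) and TSHZ2 (-1.03 ± 0.18). In all 19 probe sets passed, 2 higher and 17 lower. The count was 0 without a batch term or with batch as a random block, 6 with only the 2 groups compared and 240 with array weights.

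Interferon response genes were higher by a mean of 1.00 in this comparison (20 of 23 positive; CMPK2 1.68 ± 0.38; IFI6 0.78 ± 0.17), with 16 members past the threshold adjusted over the list alone and none over all probe sets. The call was lost with an estimated correlation (adjusted p = 0.717), as were those of lipid absorption and ribosomal proteins below (adjusted p = 0.85 for each). All 5 birds lay above all controls (exact p = 0.0079, the smallest possible), and the shift was 0.93, 0.82 and 1.5 in the 3 batches. Lipid absorption was higher by 0.45 (20 of 22 positive; LIPA, the lysosomal acid lipase, 0.85 ± 0.21), and by 0.29 without the arrays in doubt (adjusted p = 0.0169) or 0.28 without control replicate 2 alone. Ribosomal protein genes had a mean of -0.34, with 0 of 55 positive, and the collagen list a mean of -0.16, which did not pass (adjusted p = 0.981). Without the arrays in doubt 24 probe sets passed, 16 of them shared and TSHZ2 (adjusted p = 0.0537) not among them, and with the index as a covariate 0 passed. The count fell to 5 without control replicate 5, 7 without lysolecithin low replicate 4, 8 without control replicate 3, 10 and 12 without lysolecithin low replicates 3 and 1, and was 41 without lysolecithin low replicate 5.

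Lysolecithin high against control in the jejunum is the comparison named in the study's title. IL8L2, a chicken interleukin 8 that attracts granulocytes, fell by 2.82 ± 0.56 (log2, SE; adjusted p = 0.0202), from 7.17 ± 1.47 to 4.33 ± 0.46 (SD, n = 5), and was below all controls in all 5 birds. MUC2, the gel-forming mucin of goblet cells, fell by 1.96 ± 0.47 (adjusted p = 0.0495), CRACD, an inhibitor of actin capping, fell by 1.74 ± 0.29, and LCORL, a transcription regulator, fell by 1.44 ± 0.23, each again in all 5 birds. The other 2 MUC2 probe sets had -1.62 and -1.19 and did not pass (adjusted p = 0.392 and 0.241). UTRN, which ties the cytoskeleton to the membrane, SPTBN5 and PIK3CB had changes of -1.63 ± 0.29, -1.56 ± 0.18 and -1.43 ± 0.18. Among the increases were SLC25A22 (1.32 ± 0.28), the lipid enzymes ABHD12 (1.17 ± 0.26), a lysophospholipase, HACD2 (1.04 ± 0.24), of fatty acid elongation, and MGLL (1.01 ± 0.24), monoglyceride lipase, and the mitochondrial ribosome protein MRPL15 (0.99 ± 0.21). IL8L2 was also lower in the jejunum than in the ileum (-2.22 ± 0.37). Jejunum segment scores were 1.82 to 5.41 in lysolecithin high birds and -5.05 to 5.01 in controls. The score was not a term in the fit, so its part in these changes was not tested. In all 318 probe sets passed, 64 higher and 254 lower. The count was 92 without a batch term, 63 with batch as a random block, 4 with only the 2 groups compared and 847 with both segments in 1 fit and the bird as a replicate block.

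The collagen list was higher by a mean of 0.62 in lysolecithin high birds (camera adjusted p = 0.0141; 19 of 22 positive), with COL3A1 at 1.65 ± 0.74, COL1A1 at 1.47 ± 0.71 and LOXL2, a collagen crosslinking enzyme, at 0.63 ± 0.18. The call was lost with an estimated correlation (adjusted p = 0.85), as were all others in this paragraph (adjusted p = 0.85, and 0.862 for the cell cycle). No member passed over all probe sets and 1 did adjusted over the list alone, and the list is the study's own choice. The per-bird mean was 0.45 ± 0.52 against -0.15 ± 0.23 in controls (SD, n = 5), with 4 of 5 birds above all controls (exact p = 0.0714), and the shift was 0.72, 0.58 and 0.75 in the 3 batches. Smooth muscle markers were higher by 0.72 (MYH11 1.98 ± 0.84), basement membrane genes by 0.69 (COL4A5 1.79 ± 0.61), other extracellular matrix genes by 0.67 and fibroblast markers by 0.50. Oxidative phosphorylation was higher by 0.27 (31 of 33 positive; NDUFS4 0.74 ± 0.18), lipid absorption by 0.37 (MOGAT2 0.65 ± 0.14; DGAT2 1.51 ± 0.43), oxidative stress genes by 0.49 (NQO1 0.95 ± 0.27) and cell cycle genes by 0.37. Interferon response had a mean of 0.27 and did not pass (adjusted p = 0.274; 0.0111 without control replicate 1).

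Without the arrays in doubt 345 probe sets passed, 231 of them shared, while MUC2 (-1.80, adjusted p = 0.0757), ABHD12 (0.0578), HACD2 (0.0617), MGLL (0.0669), MOGAT2 (0.0522) and NDUFS4 (0.0824) did not. The lipid shift was then 0.20 and did not pass (adjusted p = 0.257), and it was 0.22 without control replicate 2 alone (0.321). The call also ended without lysolecithin high replicate 2 (0.0503) or 5 (0.0542). With the index as a covariate 375 probe sets passed, 173 of them shared. The count was 105 without lysolecithin high replicate 1, 135, 149, 149 and 163 without control replicates 5, 1, 4 and 3, 191 without lysolecithin high replicate 3 or 4 and 1224 without replicate 2, and the collagen call ended without control replicate 5 (adjusted p = 0.0683) or lysolecithin high replicate 3 (adjusted p = 0.0558). Without lysolecithin high replicate 3 the basement membrane (0.0541), fibroblast (0.0538) and other matrix (0.144) calls ended, the last also without control replicate 5 (0.051). The smooth muscle call ended without control replicate 3 or 5 or lysolecithin high replicate 1, 3 or 4 (0.0572 to 0.134), and the cell cycle call without control replicate 3 or 5 or lysolecithin high replicate 3 or 4 (0.0966 to 0.389).

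Purified LPC and lysolecithin were compared in the jejunum at matched LPC levels, which asks whether the rest of the mixture adds to the effect. At the low level 0 of 38382 probe sets passed (limma; 1999 at an unadjusted p under 0.05), and at the high level 0 passed (2346), with 2 without lysolecithin high replicate 3 and 1 without replicate 5. Both counts were also 0 without the arrays in doubt (1981 and 2599 at an unadjusted p under 0.05) and with the index as a covariate. The lists that differed at the high level were led by interferon response, with a mean of -0.50 in lysolecithin high relative to LPC high birds, and cell cycle, at 0.52 (adjusted p = 0.506 for both with an estimated correlation). Brush-border genes were lower with lysolecithin by a mean of -0.19 at the low level, a call kept with an estimated correlation (adjusted p = 0.0414; exact p = 0.0873). This comparison includes jejunum LPC low replicate 4, an array in doubt with a segment score of -5.99. Of the 25 brush-border genes 12 were lower and 4 higher in the jejunum than in the ileum, so arrays nearer the ileum can move this list. Its value without that array is not given here. High against low level over both products gave 0 probe sets in the jejunum (5663 at an unadjusted p under 0.05), with 130 without LPC low replicate 5, 341 without lysolecithin high replicate 5, 530 with the index as a covariate and 0 without the arrays in doubt (4293). Its collagen list had a mean of 0.64 and its smooth muscle markers of 0.75 (adjusted p = 0.262 for each with an estimated correlation).

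LPC low against control in the ileum gave few calls. CDX2, a transcription factor that sets intestinal identity, rose by 0.71 ± 0.10 (log2, SE; adjusted p = 0.0145), from 9.54 ± 0.14 to 10.26 ± 0.26 (SD, n = 5), in all 5 birds. PDCD6, a calcium-binding protein of vesicle traffic, rose by 0.69 ± 0.12 and DENND2D, an exchange factor for Rab GTPases, by 0.65 ± 0.12, and ZNRF2, a ubiquitin ligase, fell by 1.43 ± 0.26 (adjusted p = 0.0498 for each). No other probe set of these genes passed. The others had -0.0665 and 0.282 for CDX2 and 0.0376 to 0.405 for PDCD6. For DENND2D the other had 0.86, and for ZNRF2 they had -0.31 to -0.052. In all 12 probe sets passed, 3 higher and 9 lower, of which 8 carry no gene symbol. The count was 2 with only the 2 groups compared, 6 with arrays centred on their median and 1084 with array weights. Lipid absorption was higher by 0.49 (20 of 22 positive; APOA4 1.38 ± 0.53; DGAT2 1.34 ± 0.41; adjusted p = 0.661 with an estimated correlation) and interferon response by 0.63 (20 of 23 positive; 3 members adjusted over the list alone and none over all probe sets; 0.661 likewise as an adjusted p). The interferon shift was 0.58, 0.86 and 0.56 in the 3 batches and the lipid shift 1.29, 0.23 and 0.42. Without the 2 LPC low arrays in doubt, which leaves 3 birds against 5, 2297 probe sets passed, 759 higher and 1538 lower, with all 12 among them, KRT23 at 2.64 ± 0.50 and JUP at 2.19 ± 0.33 (both chosen after their values were seen), and the lipid list did not pass (0.33, adjusted p = 0.0618; 0.24 without LPC low replicate 1 alone, adjusted p = 0.225). With the index 7 passed, and leaving out any 1 of the 10 birds gave between 1 (without control replicate 4, for example) and 777 (without LPC low replicate 1).

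LPC high against control in the ileum left 0 of 38382 probe sets past the threshold (limma; 3828 at an unadjusted p under 0.05), with 1 without control replicate 4, 4 without LPC high replicate 1, 93 with array weights, and 0 without the arrays in doubt (4327) or with the index as a covariate. The leading values were ITGB4, an integrin of epithelial anchorage, at 0.85 ± 0.16 (log2, SE; adjusted p = 0.133), MYO15L at 1.07 ± 0.20 and ZNF292 at -0.95 ± 0.18. As a list, cell cycle genes were lower by a mean of -0.54, with 3 of 34 positive, led by CENPF (-0.98 ± 0.25), and MKI67, a proliferation marker, had -1.17 ± 0.38 (adjusted p = 0.311). This call was lost with an estimated correlation (adjusted p = 0.462), as were those below (0.462 for the crypt and interferon lists, 0.523 for ribosomal proteins, and 0.661 for matrix, collagen and lipid absorption, likewise as adjusted p). Adjusted over the list alone 21 members were lower, and none over all probe sets. Control replicate 2 stood apart on this list (1.09, the other controls -0.15 to 0.14), and without it the mean was -0.32 (adjusted p = 5.71e-08). Crypt stem cell genes had a mean of -0.41 (EPHB2 -0.89 ± 0.25; -0.27 without control replicate 2), ribosomal protein genes of -0.36 and other extracellular matrix genes of -0.46 (SPARC -1.51 ± 0.47). The collagen list was lower by a mean of -0.58 (camera adjusted p = 0.00414), opposite in sign to the jejunum, with COL1A1 at -1.87 ± 0.60, COL3A1 at -2.15 ± 0.77 and 5 members lower adjusted over the list alone. Smooth muscle markers had a mean of -0.44 in these birds, which did not pass (adjusted p = 0.193; -0.76, -0.64 and 0.31 in the 3 batches), and with the index as a covariate, which was higher in these birds, the collagen list had an adjusted p of 0.0297. All 5 birds lay below all controls for the cell cycle, crypt, matrix and collagen lists (exact p = 0.0079 for each, adjusted p = 0.0855). Within the 3 batches the collagen shift was -0.84, -0.56 and -0.21, and the cell cycle shift -0.86, -0.42 and -0.14. Lipid absorption was higher by 0.33 (FABP2, the intestinal fatty acid binding protein, 0.78 ± 0.23, adjusted p = 0.287) and interferon response by 0.75 (0.50 without LPC high replicate 3). The collagen call ended without LPC high replicate 1 (adjusted p = 0.0656).

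Lysolecithin low against control in the ileum had the highest mean of the interferon list among the comparisons with control. This ranking was not tested. RSAD2, an antiviral enzyme, rose by 4.27 ± 0.76 (log2, SE; adjusted p = 0.0119), a 19.3-fold difference, from 6.29 ± 1.18 to 10.56 ± 0.76 (SD, n = 5). IFIT5, which binds viral RNA, rose by 3.07 ± 0.51, SAMD9L, an interferon-induced restriction factor, by 2.88 ± 0.53, CMPK2, a nucleotide kinase, by 2.34 ± 0.44, OASL, of the oligoadenylate synthetase family, by 2.19 ± 0.40, and IFIH1, a sensor of viral RNA, by 2.09 ± 0.38. SLBP, the histone stem-loop binding protein, rose by 3.78 ± 0.65. EHBP1, of endocytic traffic, fell by 1.99 ± 0.28, PLCB4, a phospholipase, fell by 1.57 ± 0.30, GNPTAB, of lysosomal enzyme sorting, fell by 1.54 ± 0.25, VIM, a filament of mesenchymal cells, fell by 1.51 ± 0.29, and SLC4A4, a bicarbonate transporter, fell by 1.25 ± 0.22. In these 12 genes all 5 birds lay beyond all controls, and all were past the threshold without the arrays in doubt and with the index. In all 336 probe sets passed, 172 higher and 164 lower. There were 174 without a batch term, 161 with batch as a random block and 601 with both segments in 1 fit and the bird as a replicate block.

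Of the 23 interferon genes, 15 rose over all probe sets and 19 adjusted over the list alone, with a mean of 1.5 (camera adjusted p = 7.97e-24; 0.421 as the adjusted p with an estimated correlation). Fry gave the list an adjusted p of 0.00258, all 5 birds lay above all controls (exact p = 0.0079, adjusted p = 0.0855), and the shift was 1.52, 1.28 and 1.88 in the 3 batches. Ribosomal protein genes had a mean of -0.49, with 10 of 55 lower over all probe sets and 54 adjusted over the list alone, led by RPS15A (-0.60 ± 0.12) and RPL3 (-0.62 ± 0.13; adjusted p = 0.462 for the list with an estimated correlation). Lipid absorption was higher by 0.48, and LIPA rose by 1.26 ± 0.25 (adjusted p = 0.661 for the list with an estimated correlation). Oxidative stress genes had a mean of -0.39 (0.659 likewise as an adjusted p), and MUC2 had -1.18 ± 0.33 (adjusted p = 0.0845). Without the arrays in doubt, none of which is in these groups, 663 probe sets passed, 334 of them shared, and with the index 293 passed. The count fell to 21, 103 and 170 without control replicates 3, 2 and 4 and to 42, 131 and 196 without lysolecithin low replicates 1, 5 and 3, and was 554 without control replicate 5.

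Lysolecithin high against control in the ileum gave mostly lower values. MUC2 fell by 1.74 ± 0.34 (log2, SE; adjusted p = 0.03), from 9.76 ± 0.83 to 8.23 ± 0.72 (SD, n = 5), below all controls in all 5 birds. The other 2 MUC2 probe sets had -0.39 and 0.37 (adjusted p = 0.809 and 0.876), so the fall rests on 1 of 3. B3GALT5, a galactosyltransferase of glycan synthesis, fell by 1.73 ± 0.31, PCNT, a centrosome protein, by 1.39 ± 0.23, MGA, a transcription regulator, by 1.34 ± 0.20, and ZNF236, ARFGEF1 and RALGAPA2 had changes of -1.33 ± 0.23, -1.28 ± 0.19 and -1.27 ± 0.18. ARFGEF1 has no other probe set, and no other one passed for the rest. Those had -2.69 for B3GALT5, -0.505 to 0.0431 for PCNT and -0.532 to 0.412 for MGA. For ZNF236 they had -0.701 to 0.102, and for RALGAPA2 the other had -0.108. ACSF2, an acyl-CoA synthetase, rose by 1.03 ± 0.20 and PLA2G7, a phospholipase that cleaves oxidised phospholipids to lysophospholipids, rose by 0.98 ± 0.19, both in all 5 birds. In all 83 probe sets passed, 4 higher and 79 lower. There were 0 without a batch term or with batch as a random block, 2 with only the 2 groups compared and 160 with both segments in 1 fit and the bird as a replicate block. Lipid absorption was higher by a mean of 0.54 (20 of 22 positive; FABP2 0.83 ± 0.23; APOB 0.41 ± 0.17; 1 member adjusted over the list alone and none over all probe sets) and ER stress genes had a mean of -0.22 (HSPA5 -0.43 ± 0.14), below all controls in all 5 birds (exact p = 0.0079, adjusted p = 0.0855). Neither was kept with an estimated correlation (adjusted p = 0.462 for each). Interferon response was higher by a mean of 0.44 (21 of 23 positive; no member adjusted over the list alone; adjusted p = 0.718 with an estimated correlation), by 0.52, 0.14 and 0.82 in the 3 batches and by 0.29 without lysolecithin high replicate 5. The lipid shift was 0.26, 0.24 and 1.04 in the 3 batches, and 0.34 without lysolecithin high replicate 4 and the other arrays in doubt (adjusted p = 0.000105). Without the arrays in doubt 23 probe sets passed, 20 of them shared, and MUC2 (-1.40, adjusted p = 0.0502), B3GALT5 (0.0502), ZNF236 (0.0737) and ACSF2 (0.091) did not pass, while with the index 86 passed, 51 of them shared. The count was 9, 20 and 54 without control replicates 5, 3 and 1, 12, 16 and 26 without lysolecithin high replicates 4, 3 and 2, and 156 without replicate 5.

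At the matched low level in the ileum, lysolecithin birds had higher KLHL3 (1.39 ± 0.24), an adaptor of ubiquitin ligases, NDC80 (1.34 ± 0.20), of the kinetochore, and TNFSF10 (1.22 ± 0.20), a death receptor ligand, than LPC birds. IFT88, of the cilium, was lower by -0.73 ± 0.10 (log2, SE; adjusted p = 0.00993) and ZNF706 by -0.67 ± 0.10, and each of the 5 genes separated all 5 birds from all 5. Past the threshold were 14 probe sets, 9 higher and 5 lower, and 1010 without the arrays in doubt, and 16 with the index as a covariate (12 of them shared). With only the 2 groups compared 0 passed, with 41 without a batch term and 192 with array weights. Leaving out 1 bird gave 0 without LPC low replicate 5 or lysolecithin low replicate 5, 1 without LPC low replicate 3, 3, 6 and 9 without lysolecithin low replicates 1, 3 and 4, 72 and 97 without LPC low replicates 2 and 1, and 654 without lysolecithin low replicate 2. Interferon response was higher with lysolecithin by 0.87 and ribosomal protein genes lower by a mean of -0.39 (adjusted p = 0.747 for each with an estimated correlation).

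At the high level 0 probe sets differed between the products in the ileum (limma; 1336 at an unadjusted p under 0.05; 1 without LPC high replicate 4; 0 without the arrays in doubt, with 1020, and 0 with the index as a covariate). High against low level gave 0 (4263 at an unadjusted p under 0.05), with 595 without the arrays in doubt, 6 with the index as a covariate, 18 without LPC low replicate 1, 17 without LPC high replicate 3 and 1 without lysolecithin low replicate 5. Interferon response was lower at the high level by a mean of -0.47 in the ileum and -0.45 in the jejunum (adjusted p = 0.997 and 0.262 with an estimated correlation).

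**Figure D3:**
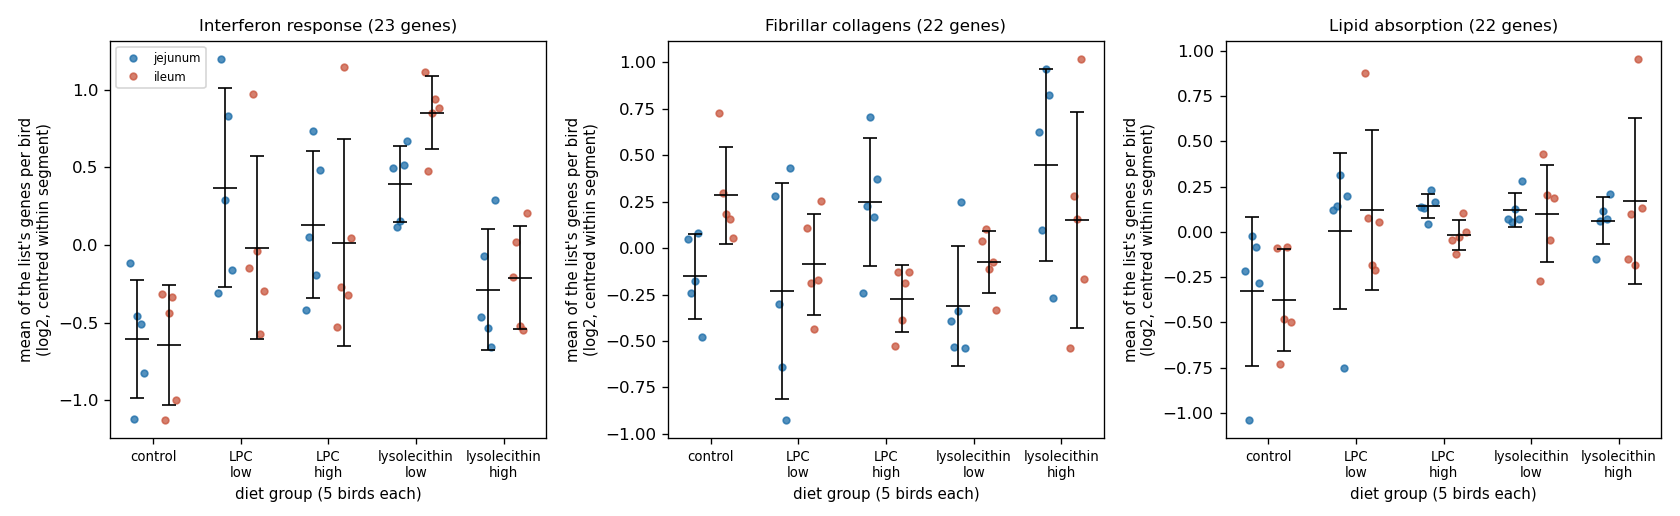
Mean centred log2 signal per bird (vertical axis) of the interferon, lipid absorption and collagen lists by diet (horizontal axis), jejunum in blue and ileum in red, with 1 point per bird and bars for the mean and SD of 5 birds. In the ileum the 5 lysolecithin low birds lie above all 5 controls for the interferon list.

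Any effect of diet was asked with an F-test over the 4 diets. In the jejunum 50 probe sets passed, led by SPTBN5, INO80D, a chromatin remodelling subunit, and ZNF236 (adjusted p = 0.00561 for the first and 0.00565 for the others), and 27 passed without the arrays in doubt, 84 with the index. In the jejunum 0 passed without a batch term or with batch as a random block, and 284 with array weights. In the ileum 53 passed, led by IFT88 (adjusted p = 0.0318) and MAP7, a microtubule protein (adjusted p = 0.0333), and 1348 passed without the arrays in doubt, 139 with the index. In the ileum 5 passed without a batch term or with batch as a random block, and 764 with array weights. Both counts moved with single birds, between 18 (without control replicate 5) and 89 (without lysolecithin high replicate 5) in the jejunum and between 0 (without control replicate 3, for example) and 318 (without LPC low replicate 1) in the ileum.

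Whether diet effects differed between segments was tested on the within-bird differences. TMEM248, a membrane protein, passed (adjusted p = 0.0364) together with 1 probe set that carries no gene symbol (adjusted p = 0.00928), out of 38382 (3951 at an unadjusted p under 0.05), and 0 passed without the 4 birds in doubt and 1 with the index difference as a covariate. The difference in collagen shift between jejunum and ileum was 1.03 for LPC high (adjusted p = 0.512 with an estimated correlation) and 0.77 for lysolecithin high (0.512 likewise as an adjusted p).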

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

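The tests of exchanged tubes, the fits without the arrays in doubt and with the index as a covariate, and the tests of the index against the calls of both LPC low comparisons, jejunum lysolecithin low and ileum lysolecithin high were chosen after the result was seen. An array was singled out when its gap to the nearest of the other 4 birds of its group was large against the group's range. This happened in 23 of 232 groups of 5, and chance flags about 1 in 20 groups, or 11.6 here. Differences between the segments were singled out by a test of the difference, and the index because it lies outside the comparisons of the report.

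The segment score stood apart in ileum LPC low replicate 1 (3.51, the nearest other -4.56), ileum lysolecithin high replicate 4 (3.35, nearest -5.42) and jejunum lysolecithin high replicate 3 (1.82, nearest 4.72). Lipid absorption, whose camera call between the segments was lost with an estimated correlation (adjusted p = 0.342), did so in the 4 arrays on the side of the other segment: 0.88 in ileum LPC low replicate 1, 0.95 in ileum lysolecithin high replicate 4, -1.04 in jejunum control replicate 2 and -0.75 in jejunum LPC low replicate 4. Its members SCARB1 and CD36 are among the genes most biased to the jejunum, so this is not independent of the segment score. Cell cycle genes stood apart in ileum control replicate 2 (1.09) and ileum LPC low replicate 1 (0.19), and ZNF706 in the latter (10.95).

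An exchange of tubes between birds is excluded among these 50 arrays for the out-of-place arrays of control replicate 2, LPC low replicate 1 and lysolecithin high replicate 4, since 0 of the 3 matched another bird (lowest match to their own bird 0.86, highest to another 0.419). For LPC low replicate 4, whose 2 arrays matched each other at 0.316, the best match to another bird was 0.456, below the lowest own match of the other birds (0.736), so no partner among these birds was found. For an exchange of both tubes of 1 bird, 0 of 4 birds had both arrays out of place. It is excluded for control replicate 2, LPC low replicate 4 and lysolecithin high replicate 4, whose other array scored on its own side (-5.68, -4.56 and 4.96). For LPC low replicate 1 it stays open, since its scores were in reverse order (ileum 3.51, jejunum -1.40). That jejunum score is the lowest of those kept, though above all ileum arrays kept (highest -4.56). A single wrong label, sampling from the neighbouring segment, a tube from outside the study and repeated extraction stay open, as does repeated hybridisation of the same RNA for control replicate 2, whose arrays differed by an SD of 0.21 (next lowest 0.32, median 0.48). No biological explanation was tested.

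The 5' minus 3' index was higher than in controls by 0.51 in jejunum LPC high, 0.31 in jejunum lysolecithin low, 0.24 in ileum LPC high and 0.25 in ileum lysolecithin high birds. Within the 3 batches the jejunum LPC high difference was 0.62, 0.38 and 0.56. Ileum control replicate 5 had an index of -1.04, against -0.75 to -0.72 in the other controls.

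In none of the 7 comparisons with control that had calls did a linear effect of this index give the whole change. Whether RNA integrity or labelling did so stays open. The index is a noisy measure of it, so slopes within groups can be too small. The called probe sets were also chosen for a large difference between groups. The slope of each probe set on the index within groups gave a median share of the change of 0.242 (0.193 to 0.295 with 1 bird left out) over the 43 calls of jejunum LPC high, 0.0634 (0.00826 to 0.173) for the 1 of jejunum LPC low, 0.0652 (0.00548 to 0.0907) for the 19 of jejunum lysolecithin low and 0.0026 (-0.0132 to 0.0372) for the 318 of jejunum lysolecithin high. In the ileum it was 0.0355 (0.0094 to 0.0621) for the 12 of LPC low, 0.0127 (0.00355 to 0.0251) for the 336 of lysolecithin low and -0.0138 (-0.0449 to 0.0102) for the 83 of lysolecithin high. With the index as a covariate the counts of jejunum LPC high, lysolecithin low and LPC low fell to 0, as median sizes went from 0.95 to 0.60, from 0.99 to 0.90 and from 1.66 to 1.55 while the SE went from 0.166 to 0.194, from 0.16 to 0.17 and from 0.233 to 0.249. How much of the change came through RNA quality stays open, and whether diet itself changes RNA integrity in the gut was not tested.

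Diet effects on lists differed between the segments (jejunum minus ileum) in 20 of 140 tests that passed both camera (adjusted) and the exact permutation (unadjusted), out of 42 that passed camera. None passed the permutation when adjusted (lowest adjusted p = 0.0855) or camera with an estimated correlation (lowest adjusted p = 0.512). For LPC high the differences were 1.03 for collagens, 0.94 for smooth muscle, 0.93 for other matrix, 0.78 for basement membrane, 0.53 for macrophages, 0.46 for fibroblasts, 0.39 for the cell cycle, 0.27 for TGF-beta signalling, 0.26 for ribosomal proteins and -0.45 for inflammatory cytokines. For lysolecithin high they were 0.77 for collagens, 0.62 for basement membrane, 0.54 for crypt stem cells, 0.53 for fibroblasts, 0.51 for oxidative stress, 0.32 for oxidative phosphorylation, 0.32 for ribosomal proteins and 0.28 for TGF-beta signalling. Interferon response differed by -0.50 for lysolecithin low, and T and NK cell markers by -0.28 for LPC low. Among probe sets, TMEM248 (adjusted p = 0.0364) and 1 without a gene symbol (adjusted p = 0.00928) passed.

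The higher collagen list in the jejunum at the high level may reflect more of the muscle layer in those scrapings. With the smooth muscle score as a covariate, the difference went from 0.442 to 0.045 (-0.173 to 0.263) for LPC high and from 0.622 to 0.0578 (-0.173 to 0.289) for lysolecithin high. The 2 scores share 0 genes and correlated at 0.939 within diets and batches, while MYH11, a muscle myosin, had 1.94 and 1.98 in these comparisons. With the index as a covariate the collagen difference was 0.817 (0.167 to 1.47) for lysolecithin high. A linear effect of this index thus did not account for it, though the index is a noisy measure of RNA integrity. For LPC high the difference was 0.754 (-0.0022 to 1.51), where the wide interval leaves this open. An effect of diet on muscle and matrix together stays open and was not tested.

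Other single birds stood apart as follows. Smooth muscle markers were 0.51 in ileum LPC low replicate 5, -0.44 in ileum lysolecithin low replicate 5 and 0.19 in jejunum lysolecithin low replicate 4, which also had a collagen mean of 0.25. RSAD2 (9.23), IFIT5 (10.82) and IFIH1 (9.56) were lowest in ileum lysolecithin low replicate 2. VIM (7.58) and SLC4A4 (8.16) were highest in ileum control replicate 5, CDX2 (9.78) in ileum control replicate 3 and PDE1A (2.95) in ileum control replicate 4, and SLC25A22 (7.57) was lowest in jejunum lysolecithin high replicate 2.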

How the results depend on the processing

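The fits without the arrays or birds in doubt, with the index as a covariate, the exact permutation of list means and the leaving out of single birds for lists other than collagen or for the segments within a diet were chosen after seeing the data. Counts are probe sets past the threshold, and for the collagen list the adjusted p of camera. Where no cause is given, the cause was not tested. Counts that are not named under a setting stayed within 1.5 times the reported count. The diets are set against control unless said otherwise.

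Without a batch term, jejunum lysolecithin high had 92 calls (318 reported), jejunum lysolecithin low 0, ileum lysolecithin low 174, ileum lysolecithin high 0, any diet 0 in the jejunum and 5 in the ileum, and ileum lysolecithin low against LPC low 41, and the collagen list passed in ileum LPC low (0.0478). With batch as a random block the counts in the same order were 63, 0, 161, 0, 0, 5 and 41, and jejunum LPC high had 2.

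With only probe sets above the median level, so that fewer were tested, counts were 97 in jejunum LPC high, 31 in ileum LPC low, 514 in ileum lysolecithin low, 128 for any diet in the ileum and 34 for ileum lysolecithin low against LPC low, and the collagen list did not pass in jejunum lysolecithin high (0.0993). A trend and robust prior gave 81 for any diet in the ileum and 1 for the difference of diet effects between segments.

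Array weights gave 908 calls in jejunum LPC high, 26 in jejunum LPC low, 240 in jejunum lysolecithin low, 284 for any diet in the jejunum, 93 in ileum LPC high, 1084 in ileum LPC low, 515 in ileum lysolecithin low, 131 in ileum lysolecithin high, 764 for any diet in the ileum, 192 for ileum lysolecithin low against LPC low and 8 for the level in the ileum.

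Without the arrays in doubt, there were 8 calls in jejunum LPC high, 0 in jejunum LPC low, 27 for any diet in the jejunum, 2297 in ileum LPC low, 663 in ileum lysolecithin low, 23 in ileum lysolecithin high, 1348 for any diet in the ileum, 1010 for ileum lysolecithin low against LPC low and 595 for the level in the ileum. The collagen list passed in ileum lysolecithin high (0.0310), and its p in jejunum LPC low, where it did not pass, was 0.417. The difference of diet effects between segments had 0 calls without the birds in doubt.

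With the index as a covariate, there were 0 calls in jejunum LPC high, jejunum LPC low and jejunum lysolecithin low, 84 for any diet and 530 for the level in the jejunum, 7 in ileum LPC low, 139 for any diet and 6 for the level in the ileum, and 1 for the difference between segments. The collagen list, short of the threshold, had 0.297 in jejunum LPC low and 0.743 in jejunum lysolecithin low.

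With both segments in 1 fit and the bird as a replicate block, counts were 198 in jejunum LPC high, 14 in jejunum LPC low, 35 in jejunum lysolecithin low, 847 in jejunum lysolecithin high, 343 for any diet, 145 for the level and 2 for lysolecithin high against LPC high in the jejunum. In the ileum this block gave 601 in lysolecithin low, 160 in lysolecithin high, 320 for any diet, 103 for lysolecithin low against LPC low and 1 for the level.

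Centring each array on its median gave 6 calls in ileum LPC low, 30 for any diet in the jejunum, 9 for ileum lysolecithin low against LPC low and 1 for the difference between segments, and a collagen p of 0.0498 in ileum LPC low. With only the 2 groups compared, there were 443 calls in jejunum LPC high, 6 in jejunum lysolecithin low, 4 in jejunum lysolecithin high, 2 in ileum LPC low, 2 in ileum lysolecithin high and 0 for ileum lysolecithin low against LPC low. Jejunum against ileum gave 5 calls in the 5 control birds alone and 883 without control replicate 2, the pair in doubt, while leaving out another control gave 0 to 6. The 5 birds of LPC high and lysolecithin low, none in doubt, gave 2861 (1378 to 2977 with 1 bird left out) and 869 (301 to 1163). LPC low, with 2 birds in doubt, gave 0 (0 to 1), and lysolecithin high gave 0, with 369 without replicate 4, its bird in doubt. Birds in doubt were found by the segment score, so higher counts without them follow in part from that choice.

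The list calls rest on the preset correlation. Of 140 tests per segment, 33 passed in the jejunum and 31 in the ileum, and with an estimated correlation 0 passed in either or between the segments. Fry passed 0 in the jejunum, 1 in the ileum and 11 of 35 between the segments, and the exact permutation passed 0 in each segment. The smallest p of that permutation, 0.0079, passes the adjustment only if many lists reach it together. Its 0 therefore says little about the lists. The collagen list had 0.661 in ileum LPC high and 0.850 in jejunum LPC high and jejunum lysolecithin high with the estimated correlation, and 0.247, 0.330 and 0.222 with fry.

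Leaving out 1 bird in turn moved counts over these ranges. In the jejunum they were 0 to 7 for LPC low, 0 to 28 for LPC high, 5 to 41 for lysolecithin low, 105 to 1224 for lysolecithin high, 18 to 89 for any diet, 0 to 341 for the level and 0 to 2 for lysolecithin high against LPC high. In the ileum they were 1 to 777 for LPC low, 0 to 4 for LPC high, 21 to 554 for lysolecithin low, 9 to 156 for lysolecithin high, 0 to 318 for any diet, 0 to 654 for lysolecithin low against LPC low, 0 to 18 for the level and 0 to 1 for lysolecithin high against LPC high. The difference between segments ranged from 0 to 3, with 0 without lysolecithin low replicate 2, 4 or 5 and 3 without LPC high replicate 3 or lysolecithin high replicate 2, 3 or 4. The collagen p ranged from 0.000501 to 0.0662 in jejunum LPC high, 0.00267 to 0.0683 in jejunum lysolecithin high and 0.00204 to 0.0656 in ileum LPC high. Where it had not passed it ranged from 0.191 to 0.917 in jejunum LPC low, 0.0185 to 0.228 in ileum LPC low and 0.0204 to 0.982 in ileum lysolecithin high.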

Other observations

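The genes in this paragraph and the next were chosen after their values were seen, except those of the segments. LPAR5, a receptor for lysophosphatidic acid, which can be made from LPC, rose in ileum lysolecithin low birds by 1.06 ± 0.21 (log2, SE; adjusted p = 0.0197). Its values were 0.95 ± 0.22 in ileum LPC high (adjusted p = 0.19), 1.05 ± 0.26 in jejunum LPC high (adjusted p = 0.0888) and 1.02 ± 0.25 in jejunum lysolecithin low (adjusted p = 0.157). The list of 30 genes of lysophospholipid and phosphatidylcholine metabolism did not pass in any of the 8 comparisons with control, with means from 0.00 to 0.09. CTNND1, a catenin of adherens junctions, rose by 0.51 ± 0.09 in ileum lysolecithin low birds (adjusted p = 0.0136). BCL6 fell by 0.91 ± 0.18 in jejunum lysolecithin high birds (adjusted p = 0.0216). ABCC2, an export pump of the enterocyte apical membrane, had 1.55 ± 0.39 there (adjusted p = 0.0589).

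Between the segments, 3 cytochrome P450 genes were among those most biased to the jejunum: CYP1A1 was higher by 3.27 ± 0.43 and CYP1A2 by 2.96 ± 0.38, each in 24 of 25 birds, and CYP2C18 by 3.09 ± 0.44 in 23. The list of oxidative stress and xenobiotic metabolism as a whole did not pass (mean 0.26, adjusted p = 0.23; 12 of 25 members higher and 4 lower). GJB1, a gap junction protein, was higher by 3.30 ± 0.31 in 24 birds and AQP5, a water channel, by 2.91 ± 0.32 in 23. SLC5A12, a lactate transporter (-3.72 ± 0.47), SLC13A2, a dicarboxylate transporter (-2.61 ± 0.35), and HOXA13, a regulator of hindgut position (-2.95 ± 0.34), were higher in the ileum. LPCAT3, which turns LPC into phosphatidylcholine, was higher in the jejunum by 0.55 ± 0.11 in 21 birds.

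The counts were compared with those of other splits of the same birds, 100 per comparison with the real split included. Chance can be excluded for jejunum against ileum (7567, highest other split 1, 1 of 100 splits as large), where labels were exchanged within birds. The real count was also the only one of 100 as large in several tests of diet. These were jejunum LPC high (43, highest other 1), jejunum lysolecithin low (19, highest other 4), ileum lysolecithin low (336, highest other 52), ileum lysolecithin high (83, highest other 14) and any diet in the ileum (53, highest other 4). Chance is not excluded there, since the splits mixed birds over batches while the fit kept a batch term. Such splits are often less even over batches than the real groups, which can lower their counts. For jejunum lysolecithin high (318, 2 of 100), any diet in the jejunum (50, 2 of 100) and ileum LPC low (12, 4 of 100) few splits gave as many. But the highest other splits there gave 831, 388 and 2358, so chance is not excluded. Such counts point to a structure of the samples, and its source was not tested. For the difference of diet effects between segments (2), 3 of 100 splits gave as many, with 3 the highest other.

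Chance cannot be excluded for jejunum LPC low (1 probe set, TLR3; 8 of 100 splits as large, highest other 11) or ileum lysolecithin low against LPC low (14; 5 of 100, highest other 1207, which again points to a structure of the samples). Where the real count was 0 all 100 splits were as large: the highest other was 175 for jejunum lysolecithin low against LPC low, 96 for jejunum lysolecithin high against LPC high, 139 for the level in the jejunum, 1 for ileum LPC high, 1 for ileum lysolecithin high against LPC high and 3 for the level in the ileum. Nor can chance be excluded for the number of lists past camera: 23 of 100 splits reached the 33 of the jejunum (highest other 50), 13 the 31 of the ileum (highest other 41) and 29 the 9 between segments (highest other 17).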
